A study of Homo sapiens with 12 samples.

How the data were processed

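Messenger and other RNA was profiled in MD901, an established line of human diffuse large B-cell lymphoma of the germinal centre B-cell type that carries wild-type CREBBP. CREBBP encodes an acetyltransferase that acts on histones and other proteins. The cells carried 1 of 3 short hairpin RNAs against CREBBP, numbered shCREBBP.1027, shCREBBP.3753 and shCREBBP.572, or a scramble hairpin. The labels of the first hairpin number it shCREBBP.1027 in one field and 11027 in another; shCREBBP.1027 is used here. Each of the 4 groups had 3 libraries, which gave 12 libraries. Per the labels' protocols, the cells grew in IMDM with 10% serum, RNA over 200 nt was taken, and libraries followed a stranded total RNA protocol with removal of ribosomal RNA. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

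The authors deposited 1 table of 24181 rows with a value for each library. The values were read as FPKM, fragments scaled to transcript length and to the number of mapped fragments, because the submitters' processing notes name Cufflinks and the values behave as FPKM; the deposited table itself does not state the unit. The same notes name CASAVA 1.8, TopHat2 and the genome build hg19. The gene annotation, and whether values were assigned by strand, are not given in the sources used here. A row is an assembled locus with an interval and 1 or more gene names. Several names stand on 725 rows, and 5521 rows carry a name that occurs on more than 1 row. Such rows, overlapping genes, antisense genes and near-identical paralogs are uncertain, since reads may have been divided between them. Coordinates are given on hg19, counted from 1, as the interval of the assembled locus, which can be wider than the gene.

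The number of reads per library is not given in FPKM. Low values of a row lie on steps that depend on the worth of 1 read, and comparing these steps between libraries gave depths relative to scramble replicate 1. Relative depth was 1.16 and 3.62 in the other scramble libraries, 1.11 to 1.35 with shCREBBP.1027, 1.31 to 2.01 with shCREBBP.3753 and 1.27 to 1.44 with shCREBBP.572. Between 18.9% and 31.6% of low-value ratios lay on these steps, against 1.9% to 2.4% at other offsets, so whole reads were not recovered and no count test was run. No interval from read counts can be given. An exact 0 can be a failed estimate here: 754 values of 0 occurred on 390 of 11203 rows whose median was at least 1 FPKM, and such genes are described as listed at 0 with their values per library.

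Values were tested as log2(FPKM + 1) without further scaling, over the 11757 rows with a mean of at least 1 FPKM in the 12 libraries. All differences are on this scale, which understates changes of rows with low values. A linear model with a mean for each of the 4 groups was fitted with limma 3.58.1 in R 4.3.3, with a variance trend on expression, and p-values were adjusted by the Benjamini-Hochberg method over the rows of each contrast, with a threshold of 0.05. The contrasts were the mean of the 3 hairpin groups minus scramble, each hairpin minus scramble, and the 3 pairs of hairpins. An F test asked whether the hairpins differed from each other. Single genes of interest also had two-sided exact permutation tests. With 3 libraries against 3 these exact tests cannot go below p = 0.1.

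Before the data were examined, 22 gene lists were fixed: MHC class II, MHC class I, B-cell receptor signalling, BCL6-repressed genes, germinal centre B-cell identity, plasma cell differentiation, NF-kappaB targets, interferon response, p53 targets, cell cycle, MYC and ribosome biogenesis, acetyltransferases and corepressors, cAMP and CREB targets, BCL2 family, unfolded protein and amino acid stress, cholesterol synthesis, T and NK cell markers, myeloid markers, fibroblast and epithelial markers, mitochondrial transcripts, non-polyadenylated and histone transcripts, and ribosomal proteins. A member was represented by its row with the highest mean on a primary chromosome, and members sharing a row counted once. The 18 lists with at least 5 tested rows were compared with all other rows by limma's camera with a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with the rotation test fry.

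The rule for named genes was also fixed beforehand. It took CREBBP and EP300, and in the averaged comparison the 10 largest rises and 10 largest falls among called rows with the same sign with each hairpin. It took 2 called members per list with the largest change, or the member with the smallest p where none was called. It took 3 rises and 3 falls per hairpin, and the 5 rows with the smallest p between hairpins. Genes whose symbols start with MIR, SNORD, SNORA, SCARNA, RNU, RNY, RN7S or RNA5, most of them for RNAs under 200 nt, were tested but not named. These starts did not take in RNVU1-19 and VTRNA1-1, whose RNAs are also shorter than 200 nt and which the rule therefore named. Of the 73 rows that the rule took, 19 have a name that other tested rows also carry, and the values given are those of the row taken. Genes named outside this rule are marked as chosen after their values were seen. Results of some genes that the rule took are not reported here.

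The linear model was tested on simulated data with 200 changed rows of 11757. With an equal spread in all groups it recovered 83.5% of averaged changes of 1 log2 unit and 51.3% of those of 0.5, with 5.4% false calls. The scramble libraries spread more than the others in the deposited values: the median SD per row was 0.202 log2 units in scramble, 0.115 with shCREBBP.1027, 0.105 with shCREBBP.3753 and 0.124 with shCREBBP.572. With simulated spreads unequal in the same way, false calls were 32.6% of calls in the averaged comparison, 17.1% with shCREBBP.1027, 16.1% with shCREBBP.3753 and 22.4% with shCREBBP.572. A fit with a separate spread for each group was therefore added after the data were seen. Shares of false calls depend on the number of changed rows, which was 200 of 11757 in the simulations. They do not give the share of false calls in the deposited values, where more rows were called.

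Other settings fixed beforehand were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, median-ratio size factors, quantile normalization, no variance trend, array weights, the replicate number as a block, leaving out each library, fitting only the 6 libraries compared, leaving out each hairpin from the mean, and the 9 shCREBBP libraries as 1 group. Settings added after the data were seen were a robust variance prior, the separate spread per group, leaving out 386 rows with suspected failed estimates, and a correction of each library for transcript length and GC content. The rows left out were at 0 in at least 1 library and had a median of at least 1 FPKM. The loci of CAPN2, SVILP1, OTOGL, SHF, SERPINB11 and SELM stayed in, since they held values only in scramble replicate 3. Lengths and GC content came from GENCODE transcripts by gene symbol and were found for 95.9% of the tested rows. A DESeq2 alternative was planned only for a table of counts and does not apply.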

Results

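RNA levels were compared between MD901 lymphoma cells with 1 of 3 hairpins against CREBBP and cells with a scramble hairpin, to ask how loss of CREBBP changes gene expression. There were 3 libraries in each of 4 groups. Depth relative to scramble replicate 1 ranged up to 3.62, in scramble replicate 3, and the absolute number of reads is unknown. In scramble replicate 3, 6 loci held values of 203523 to 894692 FPKM and were at 0 in the other libraries, which raised its total to 4978528 FPKM against 538076 to 722976 elsewhere. Its upper quartile of 10.7 FPKM lay within the range of 9.82 to 10.9 of the other libraries. Libraries of 1 hairpin resembled each other closely, with mean Spearman correlations across genes of 0.972 to 0.985 within each hairpin group. The scramble libraries resembled each other less, with 0.942 for replicate 1, 0.959 for replicate 2 and 0.950 for replicate 3.

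CREBBP RNA (chromosome 16, 3775056 to 3930121) was not lower in the libraries labelled shCREBBP as a whole. The scramble libraries held 13.7, 7.10 and 5.82 FPKM. Libraries labelled shCREBBP.1027 held 11.4, 11.7 and 12.6 FPKM, above 2 of the 3 scramble libraries. Libraries labelled shCREBBP.3753 held 5.92, 6.16 and 6.10 FPKM, and those labelled shCREBBP.572 held 7.99, 7.53 and 6.91 FPKM. The averaged log2 difference was -0.03 ± 0.17 (SE; adjusted p = 0.933; exact permutation p = 0.905 over 220 splits). The differences were 0.47 ± 0.21 (SE) with shCREBBP.1027, -0.40 ± 0.21 with shCREBBP.3753 and -0.14 ± 0.21 with shCREBBP.572, with exact permutation p of 0.4, 0.4 and 0.9. Without scramble replicate 1 the averaged difference was 0.30 (limma adjusted p = 0.0174) and that with shCREBBP.1027 was 0.80 (limma adjusted p = 8.3e-05), both toward higher CREBBP. Without scramble replicate 3 the difference with shCREBBP.3753 was -0.63 (limma adjusted p = 0.0394). Corrected for transcript length and GC content, the difference with shCREBBP.1027 was 0.56 (limma adjusted p = 0.0173), and with array weights it was 0.70 (limma adjusted p = 2.2e-04). CREBBP differed between the hairpins (F test adjusted p = 0.0116), with shCREBBP.3753 below shCREBBP.1027 by a log2 difference of -0.87 ± 0.21 (adjusted p = 0.00678). In the main fit the target RNA was thus not called lower with any hairpin. Its rise with shCREBBP.1027 was called only in the alternatives given above. Every direction below is that of the libraries so labelled, not of a measured loss of CREBBP. EP300, the closest relative of CREBBP, shared its row with MIR1281 (chromosome 22, 41488465 to 41576128). It was lower with shCREBBP.3753, at 6.61 ± 0.47 FPKM (SD, n = 3) against 14.6 ± 8.75 in scramble (limma adjusted p = 0.0349), and was not called in the averaged comparison (log2 difference -0.23 ± 0.23 SE). The log2 difference of EP300 with shCREBBP.3753 was -0.90 (exact permutation p = 0.1, the smallest possible) and -0.47 without scramble replicate 1, where the averaged difference was 0.20.

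**Figure D1:**
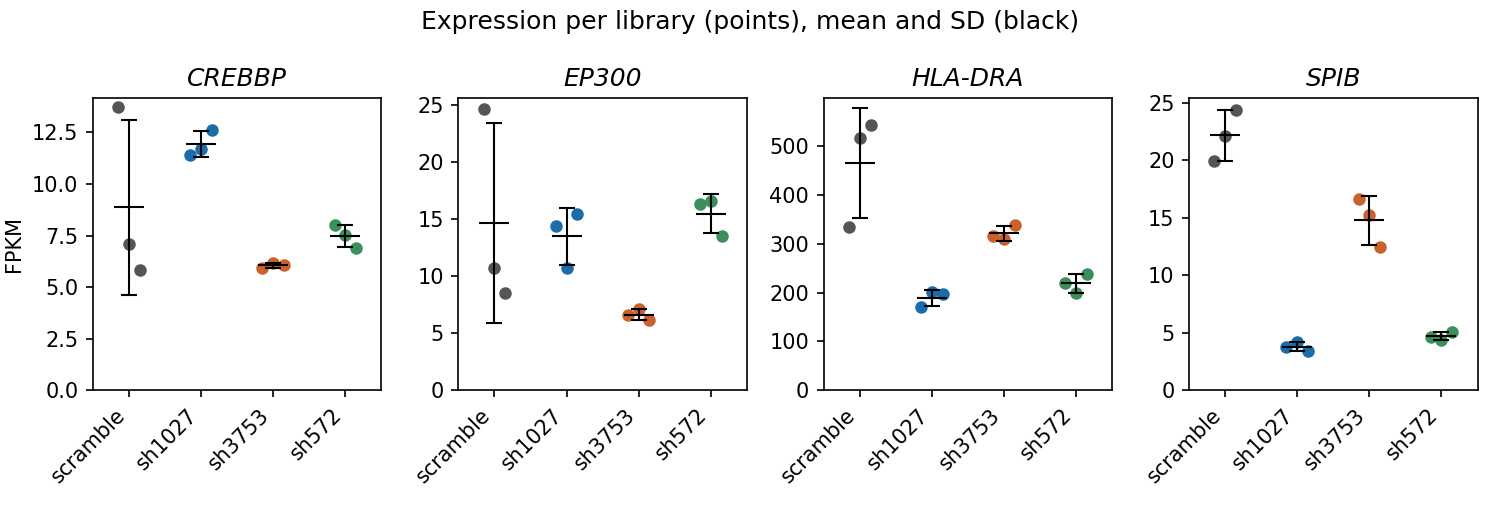
FPKM (vertical axes, starting at 0) of CREBBP, EP300 (row shared with MIR1281), HLA-DRA and SPIB in each of the 12 libraries (points), with group mean and SD (black). CREBBP of the libraries labelled shCREBBP.1027 lies at 11.4 to 12.6 FPKM, above 2 of 3 scramble libraries, while SPIB lies below every scramble library in all 9 hairpin libraries.

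Averaged over the 3 hairpins, the MHC class II, plasma cell and cell cycle lists were among those lower than in scramble by camera with the preset correlation, but none of these calls was kept with an estimated correlation (adjusted p = 0.146 for each). SPIB, a transcription factor of B cells (chromosome 19, 50922195 to 50934309), was at 22.2 ± 2.21 FPKM (SD, n = 3) in scramble and at 3.79 ± 0.39 with shCREBBP.1027, 14.8 ± 2.13 with shCREBBP.3753 and 4.70 ± 0.36 with shCREBBP.572 (averaged log2 difference -1.62 ± 0.09 SE, adjusted p = 4.3e-06). PVRIG, an inhibitory receptor of lymphocytes (chromosome 7, 99775347 to 99869855), fell by 2.19 ± 0.17 (SE; adjusted p = 1.5e-05), from 18.0 ± 2.71 FPKM to between 2.62 and 3.65 in 1 of 4 tested rows with this name, of which no other was called. BAHCC1, a chromatin reader (chromosome 17, 79373521 to 79433358), fell by 1.74 ± 0.14 (adjusted p = 1.5e-05). PTPRCAP, which binds the phosphatase CD45 (chromosome 11, 67202981 to 67205153), fell by 1.84 ± 0.13 (adjusted p = 8.7e-06). CTTN, the actin-binding protein cortactin (chromosome 11, 70244612 to 70282690), was at 0.22 ± 0.02 FPKM in scramble and at 2.75 ± 0.611, 4.37 ± 0.194 and 3.28 ± 0.465 with the 3 hairpins (1.85 ± 0.13, adjusted p = 7.0e-06). LY96, a partner of Toll-like receptor 4 (chromosome 8, 74903564 to 74941307), rose by 1.54 ± 0.19 (adjusted p = 2.0e-04). The row of KLRK1, which encodes the receptor NKG2D, with KLRC4 (chromosome 12, 10516368 to 10562771) rose by 1.59 ± 0.14 (adjusted p = 2.6e-05).

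The other rows named for the averaged comparison, except ELMO1-AS1, were listed at 0 in at least 1 library. Each value is that of the named row. Apart from TXNIP and MT1F, every gene in this paragraph has other tested rows with its name, so these values do not give the level of the whole gene. TXNIP, a regulator of thioredoxin, was at 27.2, 43.2 and 0 FPKM in the scramble libraries and at 50.7 to 83.7 FPKM in the hairpin libraries. SEC22C, of vesicle transport, was at 0, 0 and 0.526 FPKM in scramble and at 1.23 to 8.82 FPKM otherwise, and the metallothionein MT1F was at 0, 0 and 0.452 against 0.938 to 6.14. PTPLAD2 and SPDYE5 were listed at 0 in each scramble library and reached 14.8 and 5.09 FPKM in hairpin libraries, of which 2 and 1 were also listed at 0. KCNRG was at 1.59, 0 and 0 FPKM in scramble and at 0.583 to 5.29 otherwise. Among falls, RNF167, a ubiquitin ligase, was at 6.40, 6.06 and 25.2 FPKM in scramble and at 0 in all hairpin libraries except 1 of shCREBBP.572 at 7.67. The other row of RNF167 had a higher mean, 37.6 FPKM in scramble and 39.2 to 62.0 with the hairpins, and was called in the opposite direction (log2 difference 0.29, adjusted p = 0.0102), so a fall of RNF167 as a gene is not shown. The other row of SEC22C, at a mean of 8.20 FPKM in scramble, was not called (0.19, adjusted p = 0.138). LILRB3, an inhibitory receptor, was at 11.2, 1.69 and 9.96 FPKM in scramble and at 0 to 4.76 otherwise. SENP8, a NEDD8 protease, was at 5.08 to 10.6 against 0 to 5.18. The antisense genes DPYD-AS1, LIPE-AS1 and EFCAB14-AS1 were also lower and listed at 0 in some hairpin libraries. ELMO1-AS1 was at 7.01 to 31.0 FPKM against 0.482 to 13.1. DPYD-AS1 stands on 77 tested rows, of which 4 others were lower and none higher, and no other row of the remaining genes was called in the averaged comparison. Antisense genes cannot be told from their partners here.

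In all, 1349 rows were higher and 1711 lower of 11757 tested, and 2282 of these calls had the same sign with each hairpin. The median log2 difference of all rows was -0.003. A separate spread for each group left 533 higher and 913 lower rows, array weights gave 2753 lower rows, quantile normalization gave 1937 higher and 1752 lower rows (47.5% lower against 55.9%), and taking the 9 hairpin libraries as 1 group, so that differences between hairpins count as error, left 101 higher and 105 lower. Among the rows named in the preceding pair of paragraphs, CTTN (adjusted p = 8.4e-04), PVRIG (4.7e-04), BAHCC1 (0.0107), SEC22C (0.0265), MT1F (0.0367) and RNF167 (0.0261) were called in that last fit, and the others were not, among them SPIB (0.0714), PTPRCAP (0.0530), LY96 (0.0530), KLRK1 (0.0690) and TXNIP (0.110). Of the list members that the rule took and that are named below, that fit called HLA-DRA (adjusted p = 0.0496), CDKN1B (0.0362), TCF3 (0.0218), DERL3 (0.0211), FKBP11 (0.00440), SESN2 (0.0390) and RRM2 (0.00147). It did not call the others, among them HLA-DMA (0.0584), TOP2A (0.135), the row of HLA-B and HLA-C (0.345), OAS1 (0.148), LDHA (0.305), HMGCS1 (0.352) and FDPS (0.125). The calls of PTPLAD2, LILRB3, DPYD-AS1, LIPE-AS1, SENP8, EFCAB14-AS1 and ELMO1-AS1 ended with a separate spread for each group, and most of them in other alternatives too. The call of TXNIP ended with a pseudocount of 0.1 (adjusted p = 0.0664), no filter (0.141), no trend (0.0563), array weights (0.0840) and robust eBayes (0.0830), and without any single hairpin library (0.0597 to 0.0642).

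MHC class II genes, which present antigen to CD4 T cells, were lower: 11 of 15 rows fell and none rose (12 and 0 adjusted over the list alone), with a median log2 difference of -0.63 (camera adjusted p = 3.0e-07; adjusted p = 0.146 with an estimated correlation). HLA-DRA (chromosome 6, 32407619 to 32412826) was at 465 ± 113 FPKM (SD, n = 3) in scramble and at 190 ± 16.1, 322 ± 14.8 and 219 ± 19.6 with shCREBBP.1027, shCREBBP.3753 and shCREBBP.572 (-0.94 ± 0.13 SE, adjusted p = 4.6e-04). HLA-DMA, which helps load peptides, fell by 0.94 ± 0.09 (adjusted p = 3.9e-05). Chosen after their values were seen, CIITA, the master regulator of this class, fell by 0.88 ± 0.11 (adjusted p = 2.3e-04) and CD74, the invariant chain, by 0.71 ± 0.09 (adjusted p = 3.0e-04). The fit with a separate spread for each group also called 11 rows of this list lower, and the fit of 9 libraries as 1 group called 3. In MHC class I, 7 of 13 rows fell (10 adjusted over the list alone) and none rose (median -0.33, camera adjusted p = 2.5e-04; adjusted p = 0.146 with an estimated correlation). In this list the fit with a separate spread for each group called 3 rows lower, and that of 9 libraries as 1 group called 0. The row of HLA-B and HLA-C fell by 0.63 ± 0.06 (adjusted p = 4.6e-05). With shCREBBP.3753 the list was not called (2 rows rose and 0 fell; median 0.15, camera adjusted p = 0.289), and the HLA-B and HLA-C row was at 0.20 (adjusted p = 0.0607). Reads of these polymorphic paralogs may be divided between rows.

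Cell cycle genes were lower in 18 of 24 rows and higher in none (19 and 0 adjusted over the list alone; median -0.47, camera adjusted p = 3.3e-11; adjusted p = 0.146 with an estimated correlation). A separate spread for each group left 15 of these rows lower, and the 9 hairpin libraries as 1 group left 1. RRM2, of nucleotide synthesis (chromosome 2, 10262638 to 10277975), was at 117 ± 10.1 FPKM (SD, n = 3) in scramble and at 53.8 ± 2.38, 67.1 ± 3.59 and 53.2 ± 2.40 with the hairpins (adjusted p = 5.7e-06). TOP2A, a topoisomerase of dividing cells, fell by 0.73 ± 0.10 (adjusted p = 3.5e-04). With shCREBBP.572 the list was not called (2 rows rose and 4 fell; median -0.05, camera adjusted p = 0.202); the rows that rose there, chosen after their values were seen, were CCNE1 and that of E2F1 with NECAB3. It was called lower with shCREBBP.572 without scramble replicate 1 (adjusted p = 0.0435) and with array weights (0.0468). Plasma cell genes fell in 14 of 17 rows (14 adjusted over the list alone) and none rose (median -0.50, camera adjusted p = 3.0e-07; adjusted p = 0.146 with an estimated correlation). A separate spread for each group left 11 of these rows lower, and the 9 hairpin libraries as 1 group left 3. DERL3, of protein disposal from the endoplasmic reticulum, fell by 1.05 ± 0.14 (adjusted p = 3.8e-04), and FKBP11, a folding enzyme of secretory cells, by 0.93 ± 0.08 (adjusted p = 3.0e-05). Of germinal centre identity genes, 8 of 21 rows fell and 2 rose (10 and 2 adjusted over the list alone; median -0.20, camera adjusted p = 0.0105; adjusted p = 0.146 with an estimated correlation). In the same 2 fits 5 and 2 of the germinal centre rows were lower and 0 higher. With shCREBBP.1027 the germinal centre list was not called (4 rows rose and 10 fell, median -0.30, camera adjusted p = 0.215). Besides SPIB, TCF3, a B-lineage transcription factor, fell by 0.64 ± 0.06 (adjusted p = 2.7e-05). BCL6 itself was not called (-0.06, adjusted p = 0.509; chosen after its value was seen).

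Cholesterol synthesis genes fell in 10 of 17 rows (10 adjusted over the list alone) and none rose (median -0.36, camera adjusted p = 0.00183; adjusted p = 0.324 with an estimated correlation), with HMGCS1 at -0.64 ± 0.08 (SE; adjusted p = 2.1e-04) and FDPS at -0.60 ± 0.11 (adjusted p = 0.00282). By single hairpin this list was called only with shCREBBP.572: with shCREBBP.1027, 4 rows rose and 3 fell (median 0.07, camera adjusted p = 0.780), and with shCREBBP.3753, 3 rose and 2 fell (-0.15, 0.257). In the list of MYC and ribosome biogenesis, 6 of 17 rows fell (6 adjusted over the list alone) and none rose (median -0.14, camera adjusted p = 0.00824; adjusted p = 0.532 with an estimated correlation). These included LDHA, a glycolytic enzyme, at -0.61 ± 0.09 (adjusted p = 5.4e-04) and the helicase DDX21 at -0.56 ± 0.09 (adjusted p = 0.00103). Both were called lower with shCREBBP.1027 and shCREBBP.572. Neither was called with shCREBBP.3753 (LDHA at -0.05, adjusted p = 0.756, and DDX21 at -0.10, adjusted p = 0.520). By single hairpin the list was not called with shCREBBP.1027 (0 rows rose and 4 fell, median -0.10, camera adjusted p = 0.599). This list was not called without scramble replicate 2 (adjusted p = 0.0909). A separate spread for each group left 4 of its rows lower, and the 9 hairpin libraries as 1 group left 0. For cholesterol synthesis these fits left 8 and 0 rows lower. Interferon response genes rose in 7 of 18 rows and fell in 1 (8 and 1 adjusted over the list alone; median 0.23, camera adjusted p = 0.00824; adjusted p = 0.308 with an estimated correlation), with OAS1, an antiviral enzyme, at 1.24 ± 0.21 (adjusted p = 0.00153). A separate spread for each group left 2 interferon rows higher and 1 lower, and the 9 hairpin libraries as 1 group left 0 either way. By single hairpin this list was called higher with shCREBBP.3753 (median 0.90) and lower with shCREBBP.572 (-0.26, camera adjusted p = 0.00885), neither of which was kept with an estimated correlation (adjusted p = 0.0652 and 0.219). With shCREBBP.1027 it was not called (7 rows rose and 5 fell; median 0.06, camera adjusted p = 0.537). IFI44 (adjusted p = 0.00672) was at 0.209, 0.9 and 0.464 FPKM in scramble, at 1.86 to 5.45 FPKM with shCREBBP.1027 and shCREBBP.3753, and at 0.067, 0 and 0 with shCREBBP.572. This list was not called at a mean of at least 5 FPKM (adjusted p = 0.138), and IFI44 was not called with a pseudocount of 0.1 or a separate spread per group.

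Of 100 groupings of the 12 libraries, the real one included, 20 gave at least 8 called lists. Chance is therefore not excluded for the number of called lists. Other groupings mix groups that differ from each other, so they can hold list differences of their own and do not measure chance alone. The other lists were not called by camera in the averaged comparison. Of B-cell receptor genes, 3 of 19 rows rose and 7 fell (5 and 7 adjusted over the list alone; camera adjusted p = 0.185), with the phospholipase PLCG2 at 0.64 ± 0.12 (SE; adjusted p = 0.00279). Without the filter on low values this list was called lower (adjusted p = 0.0424). Of BCL6-repressed genes, 1 of 14 rose and 4 fell (1 and 4 adjusted over the list alone; adjusted p = 0.386), with the cell cycle inhibitors CDKN1B at 0.60 ± 0.12 and CDKN1A at -0.56 ± 0.09. CDKN1A was called in opposite directions, at -1.54 with shCREBBP.1027 and -0.90 with shCREBBP.572 but 0.77 with shCREBBP.3753 (adjusted p = 4.8e-04). Of NF-kappaB targets, 4 of 12 rose and 2 fell (4 and 2 adjusted over the list alone; adjusted p = 0.172), with BIRC3 at 0.76 ± 0.08 and NFKB2 at 0.50 ± 0.08. It was called higher with array weights (adjusted p = 0.0363) and without scramble replicate 1 (0.0375). Of p53 targets, 5 of 19 rose and 2 fell (5 and 2 adjusted over the list alone; adjusted p = 0.117), with BTG2 at 1.14 ± 0.06 and SESN2 at 0.59 ± 0.09. BTG2 was called higher with shCREBBP.3753 (2.07) and shCREBBP.572 (1.35) but not with shCREBBP.1027 (0.01, adjusted p = 0.919). Its averaged call ended with the 9 hairpin libraries as 1 group (adjusted p = 0.227). Of acetyltransferases and corepressors, KAT7 rose by 0.26 ± 0.05 (1 of 18 rows, and 1 adjusted over the list alone; camera adjusted p = 0.784, median -0.03 against an upward camera direction). Of cAMP and CREB targets, 1 of 13 rose and 5 fell (1 and 5 adjusted over the list alone; adjusted p = 0.386), with NR4A1 at -0.93 ± 0.17. Of the BCL2 family, PMAIP1 rose by 0.61 ± 0.07 and BIK fell by 0.38 ± 0.09 among 13 rows (1 and 1 adjusted over the list alone; adjusted p = 0.378). The BIK call ended with a separate spread per group and without scramble replicate 2 or 3. Of the stress list, 4 of 15 rose and 4 fell (6 and 5 adjusted over the list alone; adjusted p = 0.386), with the chaperones HSPA5 at -0.69 ± 0.13 and DNAJB9 at -0.61 ± 0.20. The DNAJB9 call ended in several alternatives, among them a separate spread per group (adjusted p = 0.182) and without scramble replicate 2 (0.158). Of histone and other non-polyadenylated transcripts, 1 of 10 rose and 5 fell (1 and 5 adjusted over the list alone; adjusted p = 0.128), with the row of HIST1H2AB and HIST1H3B at -0.60 ± 0.10 and that of HIST1H1E with 6 neighbouring histone genes at -0.54 ± 0.12. The latter call ended with quantile normalization (adjusted p = 0.146) and without the filter (0.345). This list was called lower without scramble replicate 1 (adjusted p = 0.00341), without the filter (0.0306) and with array weights (0.0174). No ribosomal protein gene was called among 18 (0 adjusted over the list alone; adjusted p = 0.242), while RPL30 was at 0.32 ± 0.12 (adjusted p = 0.0745). RPL30 was called higher with size factors (adjusted p = 0.0305), quantile normalization (4.3e-04) and the correction for length and GC content (0.0321). That list was called higher with quantile normalization (adjusted p = 0.00148) and without scramble replicate 3 (0.0338).

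Markers of other cell types were few. Of T and NK cell markers 3 rows were tested: ZAP70, a kinase also seen in some B-cell tumours, fell by 0.59 ± 0.07 (SE; adjusted p = 1.2e-04; 2 rows adjusted over the list alone). Of myeloid markers 3 rows were tested and none was called (0 adjusted over the list alone), with CD68 at 0.819 ± 0.312 FPKM (SD, n = 3) in scramble and a log2 difference of 0.35 ± 0.20 (SE). Of fibroblast and epithelial markers 2 rows were tested, and VIM, which lymphocytes also express, fell by 0.42 ± 0.06 (adjusted p = 4.1e-04; 1 row adjusted over the list alone). No row of the mitochondrial list was tested.

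**Figure D2:**
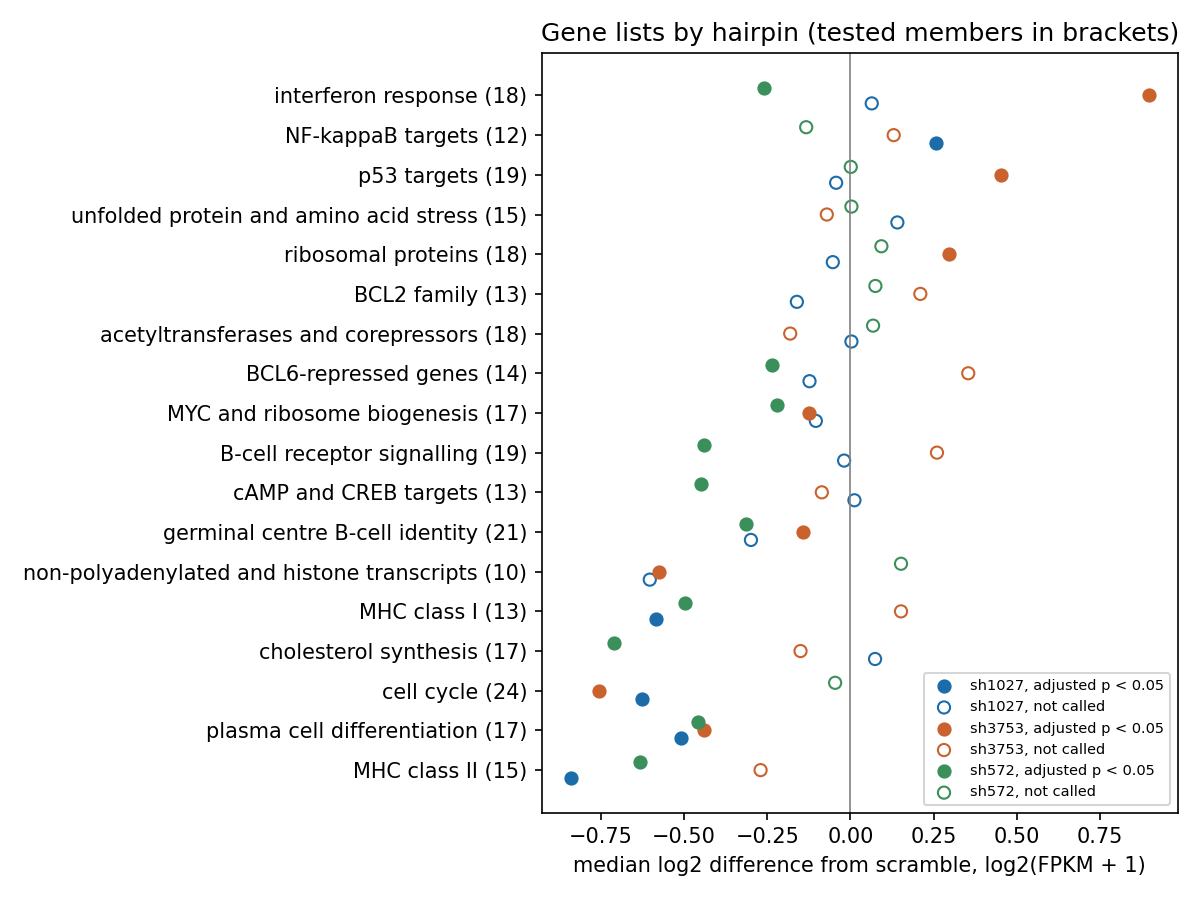
Median log2 difference from scramble (horizontal axis, log2(FPKM + 1) scale) of the tested members of each of 18 gene lists with each hairpin; filled points passed camera's preset-correlation test at an adjusted p under 0.05. Plasma cell genes lie between -0.51 and -0.44 with each hairpin, whereas interferon genes lie at 0.90 with shCREBBP.3753 and -0.26 with shCREBBP.572. The target RNA was not called lower with any hairpin in the main fit.

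In libraries labelled shCREBBP.1027, 1938 rows were higher and 2671 lower. TUBB3, a tubulin of neurons (chromosome 16, 89988417 to 90002505), was at 32.5, 36.0 and 45.5 FPKM in scramble and at 2.28 ± 0.09 FPKM with shCREBBP.1027 (SD, n = 3; log2 difference -3.56 ± 0.11 SE, adjusted p = 6.6e-09). RNVU1-19, a variant U1 small nuclear RNA, was at 3301 to 4580 FPKM in the 3 libraries of shCREBBP.1027 and listed at 0 in the other 9, on 1 of 2 tested rows with this name. The other row was at a mean of 36.4 FPKM in scramble and not called with shCREBBP.1027 (adjusted p = 0.102). RNVU1-19 and VTRNA1-1 are shorter than the 200 nt above which RNA was taken, so their yield depends on the extraction. The named rows of TMEM150A and CSMD1 were listed at 0 in scramble and at 8.61 to 17.9 and 6.15 to 32.6 FPKM with shCREBBP.1027, while single libraries of shCREBBP.3753 or shCREBBP.572 also held values. The other CSMD1 row was at a mean of 33.9 FPKM in scramble and was called lower with shCREBBP.1027 (log2 difference -0.55, adjusted p = 1.1e-04) and with each other hairpin, so a rise of CSMD1 as a gene is not shown. The other TMEM150A row was also called higher with shCREBBP.1027 (1.26, adjusted p = 0.0289). VTRNA1-1, a vault RNA, was at 267 to 420 FPKM in scramble and at 75.2, 105 and 0 with shCREBBP.1027, and its call ended with a separate spread per group, as did that of TMEM150A. The named row of RNF167 was the other fall that the naming rule took, while its other row was higher with shCREBBP.1027 (0.71, adjusted p = 7.5e-05). MHC class II (13 of 15 rows lower; median -0.84, camera adjusted p = 5.2e-06), MHC class I (10 of 13; -0.58, 8.3e-04), cell cycle (17 of 24; -0.63, 1.2e-06) and plasma cell genes (10 of 17; -0.51, 0.00142) were lower, with no row higher in any of them. None of these 4 calls was kept with an estimated correlation (adjusted p = 0.233 for MHC class II, MHC class I and cell cycle, and 0.353 for plasma cell genes). NF-kappaB targets were higher (5 of 12 rose and 1 fell; median 0.26, camera adjusted p = 0.0446; adjusted p = 0.233 with an estimated correlation), a call that ended in several alternatives, among them without scramble replicate 2 (adjusted p = 0.134). Adjusted over the list alone, 13, 11, 17 and 11 rows of the lower lists fell and none rose, and 5 NF-kappaB rows rose and 1 fell. Quantile normalization moved the share of lower calls from 58.0% to 47.4%.

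In libraries labelled shCREBBP.3753, 1895 rows were higher and 1556 lower, and interferon genes stood out. Of 18 interferon rows, 14 rose and none fell (16 and 0 adjusted over the list alone; median 0.90, camera adjusted p = 1.1e-09; adjusted p = 0.0652 with an estimated correlation). OAS1 was at 12.3 ± 2.92 FPKM against 2.46 ± 1.14 in scramble, and BST2, an antiviral tether chosen after its values were seen, at 31.9 ± 1.44 against 7.61 ± 1.19 (SD, n = 3). LGALS3BP, a secreted galectin-binding protein (chromosome 17, 76967276 to 76976061), rose from 3.03 ± 0.56 to 39.7 ± 1.54 FPKM (3.35 ± 0.12 SE, adjusted p = 4.2e-08). CD52, a lymphocyte surface antigen listed at 0 in 1 library of shCREBBP.572, was at 0.896, 0.778 and 2.18 FPKM in scramble and at 17.3, 11.96 and 18.2 with shCREBBP.3753 (adjusted p = 4.9e-05). CD37, a tetraspanin of B cells, was at 0, 0.067 and 0.064 FPKM in scramble and at 3.41 to 4.59 with shCREBBP.3753. OGN, RNF167 and LIPE-AS1 were the largest falls among the called rows that the naming rule took, each listed at 0 in at least 1 library of shCREBBP.3753. The named row of OGN was at 4.74 to 30.9 FPKM in scramble, and of 9 tested rows with this name 3 others were also lower with shCREBBP.3753. The other rows of RNF167 and LIPE-AS1 were not called with it (adjusted p = 0.345 and 0.863). Cell cycle genes fell in 20 of 24 rows and none rose (24 and 0 adjusted over the list alone; median -0.76, camera adjusted p = 5.8e-16; adjusted p = 0.0652 with an estimated correlation). The p53 targets rose in 12 of 19 rows and none fell (12 rose and 1 fell adjusted over the list alone; median 0.45, camera adjusted p = 8.1e-04; adjusted p = 0.0994 with an estimated correlation), with BTG2 at 104 ± 5.31 FPKM against 23.9 ± 1.48 (SD, n = 3). Plasma cell genes (median -0.44, camera adjusted p = 0.00256, and 0.334 with an estimated correlation), histone and non-polyadenylated transcripts (-0.58, 0.00399 and 0.588), germinal centre genes (-0.14, 0.0119 and 0.157) and MYC and ribosome biogenesis (-0.13, 0.0292 and 0.588) were lower, and ribosomal protein genes higher (0.30, 0.0370 and 0.600). Rows lower were 10 of 17, 7 of 10, 8 of 21 and 5 of 17 (10, 7, 8 and 6 adjusted over the list alone), with 1 row higher in each, and 4 of 18 ribosomal protein rows rose and 1 fell (4 and 1 adjusted over the list alone). The ribosomal protein call ended without scramble replicate 1 (adjusted p = 0.209) or replicate 1 (0.0608) or 3 (0.0627) of shCREBBP.3753, at a mean of at least 5 FPKM (0.0602) and with array weights (0.127). That of MYC and ribosome biogenesis ended without scramble replicate 2 (0.159) or 3 (0.113) or replicate 1 of shCREBBP.3753 (0.0608). MHC class II was not called (median -0.27, camera adjusted p = 0.0928) but was called lower without scramble replicate 1 (adjusted p = 0.00438), with array weights (0.0108), quantile normalization (0.0430) and the length and GC correction (0.0232). It had 2 rows higher and 6 lower. Only the 6 libraries compared gave 1209 higher and 968 lower rows, array weights 2443 lower rows, and leaving out shCREBBP.3753 replicate 3 gave 1242 higher rows.

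In libraries labelled shCREBBP.572, 1057 rows were higher and 1266 lower. Cholesterol synthesis genes fell in 14 of 17 rows and none rose (15 and 0 adjusted over the list alone; median -0.71, camera adjusted p = 2.1e-11; adjusted p = 0.0888 with an estimated correlation). HMGCS1, an early enzyme of this pathway (chromosome 5, 43287572 to 43313614), was at 14.3 ± 1.08 FPKM against 42.2 ± 4.46 in scramble (SD, n = 3). VPREB1, a surrogate light chain of B-cell precursors, fell from 15.3 ± 2.27 to 0.914 ± 0.454 FPKM (log2 difference -3.11 ± 0.17 SE, adjusted p = 9.1e-07), and ACSM1, an acyl-CoA synthetase, from 12.9 ± 4.99 to 0.716 ± 0.179 (adjusted p = 5.4e-06). EFCAB14-AS1 was at 8.18 to 9.53 FPKM in scramble and at 1.85, 0 and 0 with shCREBBP.572. Among the called rows that the naming rule took, those of SEC22C, NBPF20 and FAM174A rose most, with the latter pair listed at 0 in scramble and at 1.69 to 9.17 and 1.65 to 6.87 FPKM with shCREBBP.572. The named NBPF20 row is 1 of 22 tested rows with this name. No other row of these 3 genes was called with shCREBBP.572, and the other row of FAM174A was at a mean of 4.88 FPKM in scramble and 4.65 with shCREBBP.572, so absence of these genes from scramble is not shown. The calls of EFCAB14-AS1, NBPF20 and FAM174A ended with a separate spread per group. B-cell receptor genes fell in 13 of 19 rows and none rose (13 and 2 adjusted over the list alone; median -0.44, camera adjusted p = 2.0e-06; adjusted p = 0.0922 with an estimated correlation). MHC class II (12 of 15 rows lower; median -0.63, camera adjusted p = 1.3e-07, and 0.0922 with an estimated correlation), MHC class I (9 of 13; -0.50, 2.7e-07 and 0.0888) and plasma cell genes (10 of 17; -0.46, 1.4e-07 and 0.0888) fell. Adjusted over the list alone these counts were 12, 11 and 11, and no row rose either way. MYC and ribosome biogenesis (-0.22, 0.00143 and 0.455), cAMP and CREB targets (-0.45, 0.00885 and 0.0888), interferon (-0.26, 0.00885 and 0.219), BCL6-repressed (-0.24, 0.0242 and 0.190) and germinal centre genes (-0.32, 0.0459 and 0.190) were also lower. Rows lower were 4 of 17, 6 of 13, 7 of 18, 4 of 14 and 6 of 21 (5, 7, 7, 4 and 9 adjusted over the list alone), and rows higher were 0, 1, 0, 1 and 2 (0, 1, 1, 1 and 4 adjusted over the list alone). Without scramble replicate 1 the calls of interferon (adjusted p = 0.0532), cAMP and CREB (0.0658) and germinal centre genes (0.0704) ended, and without scramble replicate 3 that of BCL6-repressed genes (0.0595), which also ended at a mean of at least 5 FPKM (0.145). The interferon call also ended with array weights (0.0708). The germinal centre call also ended with size factors (0.0797), quantile normalization (0.0982) and array weights (0.0705), and without scramble replicate 2 (0.0582) or 3 (0.0546), shCREBBP.572 replicate 2 (0.0567) or shCREBBP.1027 replicate 1 (0.0512). Only the 6 libraries compared gave 345 higher and 620 lower rows, a separate spread per group 535 higher, array weights 2144 lower, and leaving out shCREBBP.572 replicate 1 or 3 gave 679 or 692 higher rows.

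The hairpins differed widely from each other: 6631 of 11757 rows passed the F test, and 6835 were called against scramble with at least 1 hairpin. SLAMF7, a receptor of plasma cells (chromosome 1, 160708847 to 160724713), was at 34.7 ± 1.14 FPKM with shCREBBP.1027, 178 ± 4.11 with shCREBBP.3753, 43.6 ± 2.72 with shCREBBP.572 and 73.5 ± 0.79 in scramble (SD, n = 3; adjusted p = 3.8e-09). FCRLA, of germinal centre B cells (chromosome 1, 161676762 to 161684319), was at 26.2 ± 2.34, 62.9 ± 3.19, 5.52 ± 0.63 and 31.7 ± 3.28 (adjusted p = 1.3e-08). RNVU1-19, LGALS3BP and TUBB3 were the other 3 rows with the smallest p. Against shCREBBP.1027, 2979 rows were higher and 1796 lower with shCREBBP.3753, and 2810 higher and 2066 lower with shCREBBP.572. Against shCREBBP.3753, 1726 were higher and 2111 lower with shCREBBP.572. Another scaling moved the share of lower rows between shCREBBP.3753 and shCREBBP.1027 from 37.6% to 48.3% (size factors) or 49.7% (quantile normalization).

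Rows called in the same direction with each hairpin numbered 191 higher and 247 lower, while 748 rows were called in opposite directions with a pair of hairpins. Because the comparisons share the scramble libraries, unchanged groups were simulated with the observed spreads. Over 50 simulations the mean was 0 higher and 0.06 lower rows. With no row changed, few rows pass the adjusted threshold with any hairpin, so a small overlap was fixed in advance. The simulation therefore does not measure what the shared scramble libraries add to the 191 and 247 rows. Independent lists of the observed lengths would share 28.1 and 38.1 rows. The 3 scramble libraries cannot be split into parts of at least 2, so part of the excess may come from the shared controls. Across genes, which are not independent replicates, log2 differences of hairpin pairs correlated at 0.45 (shCREBBP.1027 and shCREBBP.3753), 0.42 (shCREBBP.1027 and shCREBBP.572) and 0.45 (shCREBBP.3753 and shCREBBP.572), with simulated values of 0.78, 0.74 and 0.74. Covariances were 0.132, 0.115 and 0.105 against simulated values of 0.0876, 0.0881 and 0.0877. A separate spread for each group left 94 higher and 148 lower rows, and array weights gave 315 and 580. Quantile normalization gave 358 and 260 and moved the share of lower rows from 56.4% to 42.1%. Without scramble replicate 1 there were 432 lower rows.

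**Figure D3:**
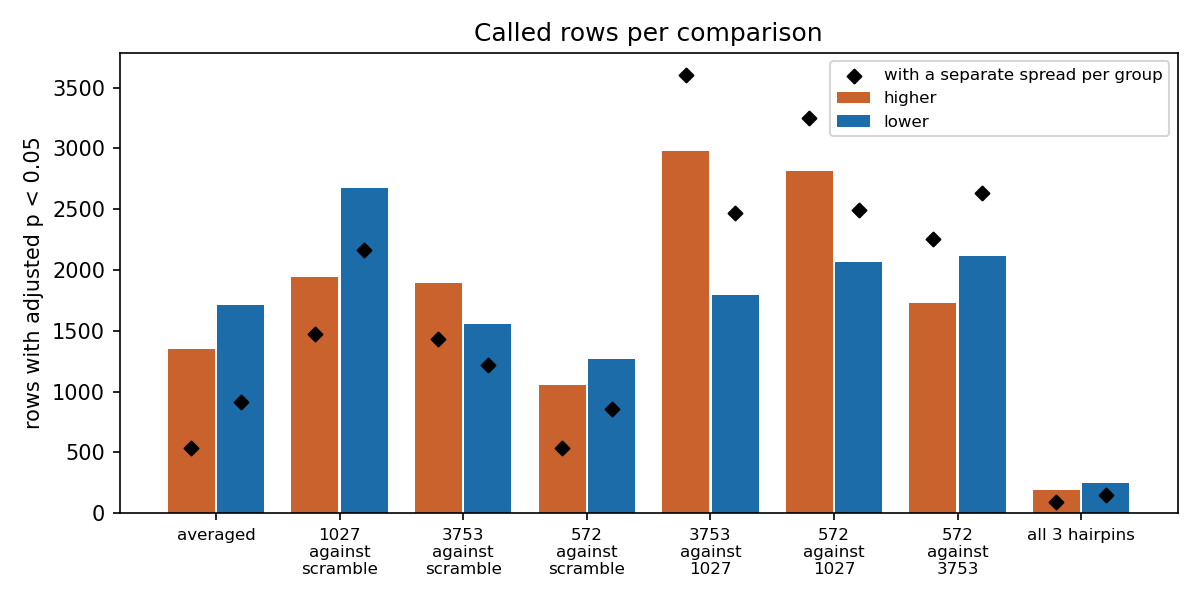
Rows with an adjusted p under 0.05 (vertical axis, bars from 0) that were higher or lower in each comparison, with black diamonds for the fit with a separate spread per group. The averaged comparison falls from 1349 and 1711 rows to 533 and 913 in that fit, while comparisons between hairpins gain rows.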

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

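Tests of exchanged labels, of a general loss of B-cell transcripts and of HLA paralogs were chosen only after the results were seen.

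The following results drew attention because they differed between hairpins in a test of the difference itself. The F test passed 6631 of 11757 tested genes or loci. Over 100 groupings of the 9 hairpin libraries into groups of 3, the real one included, no other count was above 2433. Other groupings mix the hairpins and so raise the spread within groups, which favours the real one. The count shows that the 3 sets of libraries differ, but chance differences between cultures are not excluded. CREBBP differed between hairpins at an adjusted p of 0.0116 and EP300, which shares its locus with MIR1281, at 0.0127. The smallest adjusted p were 2e-14 for RNVU1-19, 3.8e-09 for SLAMF7, 6.8e-09 for LGALS3BP, 8.2e-09 for TUBB3 and 1.3e-08 for FCRLA. Of the 73 named genes, 55 differed between hairpins.

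Of 18 gene lists, 10 differed between at least 1 pair of hairpins by camera with the preset correlation. Each is given first for its pair with the smallest p. Between shCREBBP.572 and shCREBBP.3753, adjusted p was 4.2e-10 for interferon response (0.155 with an estimated correlation), 5.0e-10 for cell cycle (0.168), 2.7e-06 for B-cell receptor signalling (0.168), 1.7e-05 for MHC class I (0.168), 0.00242 for p53 targets (0.168) and 0.00501 for non-polyadenylated and histone transcripts (0.560). Between shCREBBP.572 and shCREBBP.1027 it was 6.3e-08 for cholesterol synthesis (0.168), 0.0174 for cAMP and CREB targets (0.168) and 0.0354 for NF-kappaB targets (0.168). Between shCREBBP.3753 and shCREBBP.1027 it was 9.8e-04 for MHC class II (0.347). Most also differed in another pair. Between shCREBBP.3753 and shCREBBP.1027 these were MHC class I (1.6e-04), interferon response (2.3e-04), p53 targets (0.0138) and cell cycle (0.0185). Between shCREBBP.572 and shCREBBP.3753 they were cholesterol synthesis (1.2e-06), MHC class II (0.00148) and cAMP and CREB targets (0.0283). Between shCREBBP.572 and shCREBBP.1027 they were cell cycle (2.0e-04), interferon response (0.00868) and B-cell receptor signalling, whose adjusted p lay between these values. None was called with an estimated correlation.

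CREBBP was not lower in the libraries labelled shCREBBP as a whole. Correction for transcript length and GC content left the averaged log2 difference at 0.034 ± 0.134 (SE), which argues against such trends as the whole cause. An exchange of single labels between scramble and shCREBBP.1027 is argued against because 0 libraries of shCREBBP.1027 correlated better with scramble than with their own group. An exchange of these whole groups stays open, since 8 of the 9 libraries outside shCREBBP.1027 lay below its lowest CREBBP value. Against shCREBBP.1027, CREBBP was lower with shCREBBP.3753 (log2 difference -0.87, limma adjusted p = 0.00678) and with shCREBBP.572 (-0.61, 0.0385). By numbers of called rows shCREBBP.1027 lay furthest from the other groups: 4609 against scramble, 4775 against shCREBBP.3753 and 4876 against shCREBBP.572. Among the other groups, shCREBBP.3753 gave 3451 and shCREBBP.572 gave 2323 against scramble, and 3837 rows differed between these hairpins. Such counts can arise with or without an exchange. No value here decides whether the groups were exchanged. A weak or absent knockdown of the RNA at the time of harvest may also explain the values and was not tested.

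MHC class II genes were lower in the averaged comparison. The list stayed lower after the length and GC correction (median -0.66, camera adjusted p = 1.3e-08). Its median of -0.63 lay below the -0.18 of the 40 B-cell receptor and germinal centre genes (permutation p = 0.0014). That permutation took genes as independent, while the estimated correlation within the MHC class II list was 0.311. Plasma cell genes, which were not part of that comparison, had a median of -0.495. The test therefore does not decide on a general loss of B-cell transcripts. Reads shared between HLA paralogs are argued against by the 9 members other than the DRB, DQ and DP genes, whose median was also -0.631, with 6 called lower. A biological difference between cells with these hairpins and scramble cells may be a candidate explanation, as a hypothesis only. Loss of CREBBP is not established as its source, since CREBBP RNA was not lower, and the call was not kept with an estimated correlation (adjusted p = 0.146).

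Interferon response genes were higher in libraries labelled shCREBBP.3753. The list stayed higher after the length and GC correction (camera adjusted p = 7.9e-10). Its median of 0.90 lay at percentile 100 among 10000 random lists matched on mean expression, whose medians ran from -0.48 to 0.43, which argues against low expression and unequal depth. A response of the cells to this hairpin, through its target or otherwise, may be a candidate explanation; it was not tested, and the call was not kept with an estimated correlation (adjusted p = 0.0652).

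Other groupings of the libraries were used to ask whether the counts of calls could arise by chance. The 12 libraries were grouped 100 times into 4 groups of 3, the real grouping included. Only the real one (1 of 100) reached 3060 calls in the averaged comparison, against 773 for the next. The same held for 438 calls shared by all 3 hairpins, against 138. Other groupings mix libraries of different groups and so raise the spread within groups, which favours the real one. These counts show that the 4 sets of libraries differ. They cannot tell an effect of the hairpins from chance differences between cultures, since the replicates may be technical. For the 8 gene lists called in the averaged comparison, 20 of 100 groupings gave as many, with up to 10 in the others, so chance is not excluded. The 10 splits of 6 libraries are too few for a share under 0.05. The real and highest other counts were 4609 and 1 genes for shCREBBP.1027, 3451 and 2 for shCREBBP.3753, 2323 and 2 for shCREBBP.572, and 4775, 4876 and 3837 against 0 between hairpins. For gene lists they were 5 and 9, 8 and 9, and 10 and 10, with 4, 3 and 3 splits giving as many.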

How the results depend on the processing

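The settings chosen only after the data were seen were the robust variance prior, the separate spread per group, the removal of 386 loci with suspected failed estimates and the length and GC correction. Counts of called genes stayed within 1.5 times, and the CREBBP differences kept their side of the threshold, in the other settings not named here. Uncalled CREBBP differences crossed 0: the averaged one was 0.034 after the length and GC correction, and that with shCREBBP.572 was 0.188 without scramble replicate 1; both were also above 0 with array weights. The cause of each change below was not tested, except that fits of 6 libraries or of 1 hairpin group use fewer libraries or another error.

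Quantile normalization gave 358 higher genes shared by all 3 hairpins. Array weights gave 2753 lower genes in the averaged comparison, 2443 lower with shCREBBP.3753, 3726 with shCREBBP.572 (2144 lower), 895 shared by all 3 (315 higher, 580 lower), and a CREBBP difference of 0.701 with shCREBBP.1027. Only the 6 libraries compared gave 2177 genes with shCREBBP.3753 (1209 higher, 968 lower) and 965 with shCREBBP.572 (345 higher, 620 lower). The 9 hairpin libraries as 1 group gave 206 (101 higher, 105 lower), all also called in the averaged comparison. A separate spread per group gave 1446 averaged (533 higher, 913 lower), 1388 with shCREBBP.572 (535 higher) and 242 shared by all 3 (94 higher, 148 lower). The length and GC correction put CREBBP at 0.562 with shCREBBP.1027. With an estimated correlation, 0 gene lists were called in the averaged comparison and 0 with single hairpins. By fry, cAMP and CREB targets moved the other way with shCREBBP.3753 (adjusted p = 0.00011), and B-cell receptor, BCL6-repressed, NF-kappaB and p53 lists were called in the averaged comparison (0.0157, 0.0357, 2.7e-04 and 0.00346); fry does not compare a list with other genes.

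Leaving out 1 library gave 1242 to 2016 higher genes with shCREBBP.3753, 679 to 1140 higher with shCREBBP.572 and 184 to 432 lower shared by all 3. CREBBP ran from -0.251 to 0.303 averaged, from 0.242 to 0.797 with shCREBBP.1027 and from -0.629 to -0.074 with shCREBBP.3753. Each lowest CREBBP value was without scramble replicate 3 and each highest without scramble replicate 1. Averaged CREBBP thus turned upward without scramble replicate 1.

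The replicate block gave 3111 averaged calls (1372 higher, 1739 lower) against 3060. Correlations of the 18 same-numbered pairs of libraries ran from -0.121 to 0.162, 2 of them over 0.1. Those of other pairs ran from -0.263 to 0.176, and 6 of 12 libraries correlated best with their own number. No clear pairing by number was seen, but a weak one is not excluded. The block ended the calls of DNAJB9 (adjusted p = 0.0501) and of NF-kappaB targets with shCREBBP.1027 (0.0618) and changed no other call of a named gene or list. The DESeq2 setting was not run because the values are not counts, and the unknown number of reads leaves the precision of low values open.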

Other observations

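The test of zeros in runs was chosen only after the zeros were seen.

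Small nucleolar and Cajal body RNAs guide modification of other RNAs. Of 79 tested, 23 fell and 5 rose with shCREBBP.1027 (median log2 difference -0.46), 16 rose and 0 fell with shCREBBP.3753 (0.62), and 0 were called with shCREBBP.572 (0.24). Of 30 loci with RNU symbols, 6 fell and 0 rose with shCREBBP.1027 (median -0.05), 1 fell with shCREBBP.3753 (-0.53), and 3 fell and 1 rose with shCREBBP.572 (-0.48). Differences of these classes between hairpins were not tested. RNA over 200 nt was taken, so yields of such short RNAs depend on the extraction.

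RMRP, a long non-coding RNA of ribosomal RNA processing chosen after its values were seen, was at 123405 to 126962 FPKM in the libraries of shCREBBP.3753 and at 57204 to 87582 FPKM in the other libraries. The loci of CAPN2, SVILP1, OTOGL, SHF, SERPINB11 and SELM held 203523 to 894692 FPKM in scramble replicate 3 and 0 in the other 11 libraries.

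Loci listed at 0 in single libraries although expressed in most may have been skipped together as neighbours in the estimation of the values, as a hypothesis. Of 754 such zeros, 74 had the next expressed locus at 0 in the same library, against at most 14 in 10000 random orders (permutation p = 1e-04, the smallest they can give). A run of 40 loci on chromosome 1 in scramble replicate 3 held TXNIP and loci of NBPF20, and all 40 carried 1 shared interval. It gave a large part of the 74. The random orders took loci of 1 interval as independent, so the small p may rest largely on this run. The NBPF20 row named in the results was not counted in this run. It carries the same interval and was also at 0 in scramble replicate 3. A run of 3 ACSM1 loci on chromosome 16, also with 1 shared interval, was at 0 in replicate 3 of shCREBBP.572. The named ACSM1 row was at 0.608 to 0.923 FPKM in all libraries of shCREBBP.572. These zeros may therefore reflect a low level rather than a skipped estimate. Most zeros stood outside such pairs and have no explanation here.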
